A study of Homo sapiens with 40 samples.

How the data were processed

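RNA was extracted from frozen specimens of meningioma and meninges with a column kit, with all samples processed together, and mRNA libraries were made with an Illumina kit in technical replicates and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The submitters' processing notes name Trim Galore, STAR 2.7.11, Salmon, DESeq2 and the genome build hg38, without saying what each was used for, and the step that produced the FPKM values is not given in the sources used here. The deposited table gives FPKM values per gene symbol, 20517 genes in 40 libraries, and every column matched the title of 1 sample.

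FPKM values keep no read counts. Whole reads were looked for in low genes by dividing each gene's values by its smallest value above 0 over all libraries. Of 88334 such ratios, 14.7% lay within 0.05 of a whole number, where chance was set at 10%. The smallest value always counts as whole and libraries differ in scale, so this check cannot decide whether reads are recoverable. No read counts were recovered and no count test was run. The depth per sample is unknown here, and no counting interval or detection limit is given. Median-of-ratios factors computed from the deposited FPKM values over 13627 genes above 0 in every library lay between 1.0027 and 1.0043, so the values were already on such a scale. A gene's FPKM is therefore not relative to a fixed library total, and sums differ between libraries. Values of low genes are understated in fold change by the added pseudocount.

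Sample groups were taken from the titles and source labels. Libraries of a specimen are technical replicates per the labels' protocols, so they were averaged on the log2 scale, and specimens whose titles share a number and differ by a letter were averaged again, because they may come from 1 person. This gave 12 units, 3 meninges and 9 tumors, called replicates here and numbered in order within each group, not by the number in the titles. Before any step, 32 rows were removed, which were the X-inactivation transcripts and the genes of the Y chromosome, and 20485 genes were left. Coordinates are those of GENCODE release 29 on GRCh38, the same assembly as hg38, matched by symbol for 19950 genes (97.4%).

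Genes were kept where at least 3 units had an FPKM of at least 1, which left 14279. Differences were tested on log2(FPKM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3, using the moderated test with a trend on mean expression, two-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. Gene lists, 48 in all with 762 members, of which 758 were in the table, were tested where at least 5 members were measured (44 lists) with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. The p with an estimated correlation is given beside calls that it ended. The design, these lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the lists and the setting that the closing section says were chosen later. The procedure was tested on simulated data for the 14279 genes, with 200 genes changed: at a log2 change of 1 it made 0 calls, at 2 it called 140 genes of which 8 were false, and at 3 it called 191 of which 10 were false. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2. Noise was normal and independent between genes, with the same SD of a gene in both groups, so other genes and unequal spreads were not covered.

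The genes named were chosen by rule. They are, among protein-coding genes past the threshold whose 9 tumors all lay on 1 side of the 3 meninges, the 13 with the largest change in each direction, leaving out immunoglobulin and T cell receptor segments, HLA, hemoglobin and mitochondrially encoded genes and clone names. Added to these are up to 4 called members of each list described with the largest change (up to 2 members with the highest mean where fewer than 2 passed), and SSTR2, PGR, MUC1 and NF2 whatever their result. The rule gave 147 genes, of which 89 are printed, and these include all 81 that were called. Most of its uncalled genes were left out, by no fixed rule, and CDH5 was added outside it. FPKM means and SDs are over units. Library measures were compared with an exact two-sided permutation test over the 220 assignments of 12 units, in scripts run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and R.

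Alternatives changed the pseudocount, the filter on low values, the scaling, the unit of replication, the trend, weights for the units, the title number as a block, the set test and the units included. Shares of reads between near-identical genes depend on the submitters' counting, which is not given, so values of metallothioneins, tryptases, hemoglobins and other gene families are uncertain. Whether the libraries keep strand is not given in the sources used here.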

Results

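Messenger RNA was sequenced from resected human meningiomas, which are tumors of the membranes around the brain and spinal cord, and from resected meninges, the membranes themselves. The deposited table gave FPKM values, fragment counts scaled to transcript length and library size, for 20517 genes in 40 libraries. Of these libraries, 7 came from 3 meninges specimens and 33 from 11 tumor specimens, as 2 or 3 technical libraries per specimen. Libraries of a specimen were averaged, and 2 tumor units were each the mean of 2 specimens whose titles shared a number, which left 3 meninges and 9 tumors for the comparison. The labels do not state that the specimens came from separate people, so p-values measure the spread between these units. Read counts were not among the values used and were not recovered from them, so the depth is unknown. The FPKM values of a library summed to between 753215 and 1068835 in meninges and between 702239 and 1557340 in tumors.

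The comparison of meningioma with meninges asked which genes are expressed at different levels in the tumor. Tumors had higher levels of the cardiac muscle troponins TNNT2 and TNNC1, the tight junction protein CLDN11 and the adhesion protein CDH1 (E-cadherin). They also had higher levels of the Wnt ligand WNT6, the retinoic acid binding protein CRABP1 and the endoplasmic reticulum turnover receptor RETREG1. Meninges had higher levels of the joining chain of secreted antibodies (JCHAIN), the cartilage proteoglycan ACAN (aggrecan), the thrombospondins THBS1 and THBS4, and several markers of endothelial, mast and tendon-like cells. In total, 126 of 14279 genes were higher and 494 lower in tumor by limma's moderated test with Benjamini-Hochberg adjusted p under 0.05. Of these, 125 were higher and 488 lower by at least 2-fold on the log2(FPKM + 1) scale, on which all fold changes here are given. The 9 tumors lay above all 3 meninges for 350 genes and below them for 590, where chance alone gives 0.45% of genes in each direction. The count of higher genes fell to 62, 42 and 51 without meninges replicate 1, 2 and 3, and the count of lower genes fell to 312 without meninges replicate 1. Simulated changes of log2 size 1, 2 and 3 were recovered for 0%, 66% and 90.5% of the changed genes. These were drawn from better expressed genes, with equal spread in both groups and no correlation between genes. Under these settings smaller differences were mostly not detectable with this number of samples.

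The 13 genes that rose most, among those with all tumors above all meninges, were led by TNNT2 (chromosome 1, 201359008 to 201377762, GRCh38). Its FPKM was 4.53 ± 1.80 in meninges (SD, n = 3) and 469.2 ± 527.1 in tumors (SD, n = 9), a log2 fold change of 5.59 (SE 0.95, limma adjusted p = 0.0024). CLDN11 (chromosome 3, 170418865 to 170454733), a claudin of the arachnoid barrier and of myelin, went from 5.07 ± 2.60 to 269.3 ± 173.9 FPKM, a log2 fold change of 5.21 (SE 0.60, limma adjusted p = 0.0001). WDR86 rose from 1.65 ± 1.28 to 81.6 ± 74.2 FPKM (log2 fold change 4.68) and WNT6 from 0.668 ± 0.409 to 64.5 ± 68.9 FPKM (4.54). TNNC1, the troponin C of cardiac and slow muscle, rose from 31.4 ± 22.7 to 1409 ± 2473 FPKM, a mean that the highest tumor, at 7867 FPKM, pulled upward. RETREG1 was the most even of the group, with 4.69 ± 0.25 FPKM in meninges and 113.3 ± 57.4 in tumors (log2 fold change 4.14, SE 0.46). CRABP1 rose from 51.9 ± 45.4 to 1039 ± 920 FPKM (3.99) and CDH1 (chromosome 16, 68737225 to 68835548) from 3.08 ± 2.24 to 51.1 ± 27.7 FPKM (3.65). The hyaluronan-binding proteins CEMIP and ITIH2 had log2 fold changes of 3.97 and 3.76, and the collagen IX chain COL9A3 one of 3.48. The lipid carrier APOE had 197.4 ± 59.9 FPKM in meninges and 3177 ± 2845 in tumors (3.45), and the carboxypeptidase CPA4 had a log2 fold change of 3.39. The calls of 6 of these 13 genes, TNNT2, CLDN11, WDR86, WNT6, RETREG1 and CDH1, held in each of the 12 fits that left out 1 unit. The other 7 lost theirs in at least 1 such fit, and the highest limma adjusted p came without a meninges unit for each. APOE lost its call in 1 fit (up to 0.0864), COL9A3 in 2 (0.0922), CRABP1 in 2 (0.0994), CEMIP in 4 (0.154), TNNC1 in 5 (0.14), ITIH2 in 6 (0.147) and CPA4 in 7 (0.153).

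The 13 genes that fell most were led by JCHAIN (chromosome 4, 70655541 to 70681817, GRCh38), with 265.9 ± 242.9 FPKM in meninges (SD, n = 3) and 2.88 ± 2.59 in tumors (SD, n = 9), a log2 fold change of -6.02 (SE 0.57, limma adjusted p = 3.01e-05). ACAN (chromosome 15, 88803442 to 88875354) fell from 142.5 ± 147.2 to 1.94 ± 4.54 FPKM (log2 fold change -5.81). THBS1, a matrix protein that binds cells and activates TGF-beta, was even in meninges at 413.6 ± 58.2 FPKM and had 14.9 ± 14.9 FPKM in tumors, a log2 fold change of -5.28 (SE 0.71). THBS4, a thrombospondin of tendon, fell from 108.3 ± 98.4 to 2.67 ± 1.16 FPKM (-4.63). Other secreted matrix proteins in the group were the matrilin MATN4 (-5.25), the collagen of hypertrophic cartilage COL10A1 (-4.97) and the dermatopontin gene DPT (-4.91). CHRDL1, an antagonist of bone morphogenetic proteins, went from 35.3 ± 15.7 to 0.547 ± 0.476 FPKM and had the smallest adjusted p of the 13 (log2 fold change -4.52, SE 0.32, limma adjusted p = 2.4e-06). The smooth muscle myosin MYH11 (-4.67), the secreted glycoprotein CHI3L1 (-4.53) and the nicotinamide methyltransferase NNMT (-4.75) were also lower. The metal-binding metallothioneins MT1M (-5.47) and MT1A (-4.77) complete the 13, and their levels are uncertain because the family's genes have near-identical copies. Of these 13 calls, 12 held in each of the 12 fits that left out 1 unit, and NNMT had an adjusted p of 0.0534 and 0.07 without meninges replicate 1 and 2.

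**Figure D1:**
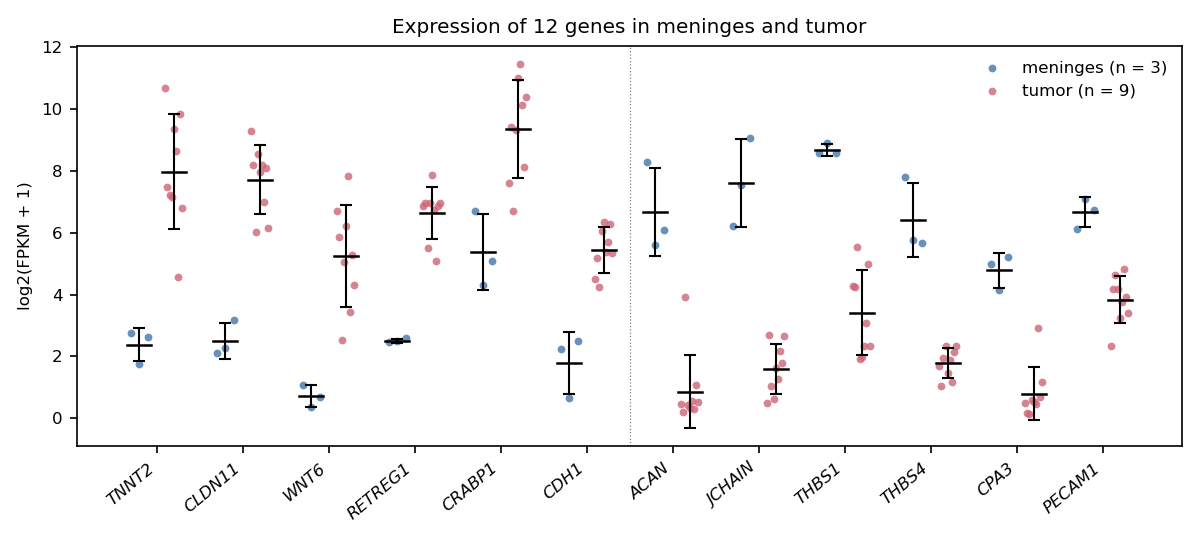
Expression of 12 genes as log2(FPKM + 1) on the vertical axis, for 3 meninges (blue) and 9 tumors (red), with 1 point per unit, the mean as a horizontal line and the SD as a bar. The 6 genes left of the dotted line rose and the 6 right of it fell, and the tumors and meninges do not overlap for any of the 12.

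Of 17 measured markers of arachnoid cap and meningothelial cells, the cells from which meningiomas are thought to arise, 6 rose in tumor and none fell, with a median log2 fold change of 1.34 (9 rose when adjusted over the list alone). Levels are those of specimens, and the share of these cells in each was not measured. A higher level per cell thus cannot be told apart from a larger share of such cells. The list passed limma's camera test with a preset correlation (adjusted p = 1.23e-07) but not with an estimated one (adjusted p = 0.0586). CLDN11 and CDH1 led the list, followed by the keratin KRT18 (9.56 ± 4.69 FPKM in meninges, 146.7 ± 185.0 in tumors, log2 fold change 3.20) and CRABP2 (90.0 ± 60.5 and 557.8 ± 353.7 FPKM, 2.67). KRT18 lost its call without meninges replicate 1 (limma adjusted p = 0.112) and 3 (0.0866), and CRABP2 without meninges replicate 2 (0.21) and 3 (0.0599) and tumor replicate 6 (0.0553). Of 12 genes used as meningioma markers, CDH1 alone was called, 3 were higher and 1 lower when adjusted over the list alone, and camera gave an adjusted p of 0.312. SSTR2, PGR, MUC1 and NF2, which were to be named whatever their result, were not called. The somatostatin receptor SSTR2 had 5.48 ± 4.57 FPKM in meninges and 31.6 ± 25.2 in tumors (log2 fold change 2.12, SE 0.68, limma adjusted p = 0.11), and passed without tumor replicate 2 (0.0167). The progesterone receptor PGR had 1.45 ± 1.18 and 5.97 ± 7.02 FPKM (log2 fold change 0.91, SE 0.79), and the mucin MUC1 15.5 ± 7.4 and 51.3 ± 62.2 FPKM (1.24, SE 0.63). The tumor suppressor NF2 (chromosome 22, 29603556 to 29698598) had 11.1 ± 4.8 FPKM in meninges and 6.72 ± 4.56 in tumors (log2 fold change -0.87, SE 0.55, limma adjusted p = 0.46). None of 18 genes recurrently altered in meningioma was called by limma, and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.692). A list written as tumor suppressors reduced in meningioma had 11 measured members. IGFBP2, an insulin-like growth factor binding protein whose place in that list was not checked, was the 1 called, and it was higher in tumor (log2 fold change 2.15). That call ended without any 1 of the 3 meninges units, with adjusted p up to 0.154. The camera adjusted p of that list was 0.907, with a median of -0.04, a mean of -0.01 and an upward sign of the test.

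Most measured markers of endothelial and mast cells fell in tumor, as did single markers of plasma cells. Of 15 endothelial genes, 11 fell and none rose (14 adjusted over the list alone), with a median log2 fold change of -2.43. Among the 4 not called, CDH5 was close to unchanged, at 29.3 ± 0.248 FPKM in meninges and 25.64 ± 9.15 in tumors (log2 fold change -0.26, limma adjusted p = 0.73). The transcription factors ERG (28.8 ± 10.1 FPKM in meninges, 2.44 ± 0.96 in tumors) and SOX17 had log2 fold changes of -3.12 and -3.08, and the endothelial surface proteins EMCN and PECAM1 had -3.11 and -2.83. PECAM1 (chromosome 17, 64319415 to 64413776) fell from 103.7 ± 33.2 to 15.2 ± 7.4 FPKM (SE 0.44, limma adjusted p = 0.0012). The endothelial list passed camera with a preset correlation (adjusted p = 4.31e-16) and with an estimated one (adjusted p = 0.0167). Of 9 mast cell genes, 7 fell (7 adjusted over the list alone), with a median of -2.01. The mast cell carboxypeptidase CPA3 fell from 27.8 ± 10.1 to 1.17 ± 2.07 FPKM (-3.99, limma adjusted p = 0.00018) and the histamine-forming enzyme HDC had a log2 fold change of -2.28. The tryptases TPSAB1 (-4.36) and TPSB2 (-3.36) are near-identical copies whose single values are uncertain. The mast cell list had an adjusted p of 5.27e-10 with the preset correlation and an adjusted p of 0.0586 with an estimated correlation. Of 6 measured B and plasma cell genes, JCHAIN and MZB1 (-1.82), an endoplasmic reticulum protein of antibody-secreting cells, fell (4 adjusted over the list alone). That list had a preset adjusted p of 0.000645 and an adjusted p of 0.0721 with an estimated correlation. MYH11 was the 1 of 12 pericyte and smooth muscle genes that fell (6 adjusted over the list alone), with an adjusted p of 0.000404 and an adjusted p of 0.0586 with an estimated correlation. Of 4 measured adipocyte genes, the fatty acid binding protein FABP4 (-4.22) and the glycerol channel AQP7 (-1.94) fell (3 adjusted over the list alone), with too few members for a set test, and AQP7 had an adjusted p of 0.173 without meninges replicate 3.

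Several genes of dense connective tissue, cartilage and bone fell in tumor, while 19 of 23 fibroblast matrix genes were not called. Of 8 genes of tendon-like fibroblasts, 4 fell (6 adjusted over the list alone), with a median log2 fold change of -3.06. They were THBS4, COMP (20.1 ± 14.3 FPKM in meninges, 0.596 ± 0.416 in tumors, -3.53), the matrix protein CHAD (-3.47) and the tendon transcription factor MKX (-2.80). The list passed camera with a preset correlation (adjusted p = 2.12e-07) and with an estimated one (adjusted p = 0.0167). Of 11 bone and cartilage genes, ACAN, COL10A1, COMP and RUNX2, a transcription factor of osteoblasts (-2.80), fell, and adjusted over the list alone 7 fell and 1 rose. The bone and cartilage list had a preset adjusted p of 1.43e-05 and an adjusted p of 0.0586 with an estimated correlation. Of 23 fibroblast matrix genes, 4 fell, and adjusted over the list alone 4 fell and 1 rose. These were the proteoglycan LUM (-3.94), the fibril-associated collagens COL14A1 (-3.57) and COL12A1 (-3.27), and THBS2 (-2.59). The list's preset adjusted p was 0.00223 and its adjusted p was 0.537 with an estimated correlation. LUM had an adjusted p of 0.0576 and THBS2 of 0.0927 without meninges replicate 1. Of 19 matrix proteases and inhibitors, 5 fell (9 adjusted over the list alone), among them the proteases ADAMTS4 (-3.51), ADAMTS1 (-3.38) and ADAMTS9 (-2.72) and the inhibitor TIMP4 (-3.36), with a preset adjusted p of 4.24e-05 and an adjusted p of 0.179 with an estimated correlation. ADAMTS4 lost its call in 10 of the 12 fits that left out 1 unit (adjusted p up to 0.29), and ADAMTS1 in 1 (0.0593 without meninges replicate 1). Of 12 genes of leptomeningeal and dural fibroblasts, CD34 (-2.52), the chemokine CXCL12 (-2.37) and DPP4 (-0.99) fell, and adjusted over the list alone 6 fell and 1 rose. CD34 is also an endothelial gene. The preset adjusted p of that list was 0.0243, its adjusted p was 0.316 with an estimated correlation, and CD34 and CXCL12 each lost their call in 2 of 12 such fits (adjusted p up to 0.0873 and 0.0798) and DPP4 in 10 (up to 0.232), each without meninges replicate 3 among others. Of 17 basement membrane genes, NID2 (nidogen) rose (1.82) and HSPG2 (perlecan) fell (-1.92), with 1 higher and 2 lower adjusted over the list alone and a camera adjusted p of 0.863. Its median was 0.23, while its mean (-0.16) and the test pointed downward. NID2 lost its call in 1 of 12 such fits (adjusted p = 0.174 without meninges replicate 2) and HSPG2 in 8 (up to 0.212).

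Few genes of inflammation and of the rapid transcriptional response were called, and those called were lower in tumor. Of 17 inflammatory cytokine and chemokine genes, 4 fell (8 adjusted over the list alone), with a median of -1.38, a preset adjusted p of 2.31e-05 and an adjusted p of 0.316 with an estimated correlation. They were CXCL2 (67.2 ± 83.6 FPKM in meninges, 2.60 ± 2.72 in tumors, -3.74), IL6 (-3.70), CCL2 (-2.97) and the prostaglandin synthase PTGS2 (-1.92). Only CXCL2 among them kept its call in every fit that left out 1 unit, while IL6 lost it in 10 of the 12 fits (adjusted p up to 0.345), CCL2 in 4 (0.255) and PTGS2 in 2 (0.193). All 21 immediate early genes had negative log2 fold changes, with a median of -1.92. MYC, a transcription factor of growth, was the 1 called (124.0 ± 85.1 and 26.3 ± 13.0 FPKM, -2.04), and 11 fell when adjusted over the list alone. FOS had 1628 ± 1351 FPKM in meninges and 317.4 ± 246.8 in tumors (log2 fold change -2.29, SE 0.71, limma adjusted p = 0.094). The immediate early list had a preset adjusted p of 2e-08 and an adjusted p of 0.386 with an estimated correlation, and MYC had an adjusted p of 0.143 without meninges replicate 1 and 0.082 without meninges replicate 2. Of 22 interferon-stimulated genes, IFI44L (-2.74), IFI44 (-1.91) and OAS2 (-1.51) fell (4 adjusted over the list alone), and they lost their calls in 2, 7 and 2 of the 12 fits that left out 1 unit (adjusted p up to 0.1, 0.233 and 0.134), each without meninges replicate 1 and 3 among others. That list had a preset adjusted p of 7.12e-06 and an adjusted p of 0.429 with an estimated correlation. Of 13 antigen presentation genes, the transactivator NLRC5 fell (-1.37, 4 adjusted over the list alone), with a preset adjusted p of 0.00223 and an adjusted p of 0.492 with an estimated correlation. NLRC5 had an adjusted p of 0.197 without meninges replicate 1 and 0.0604 without meninges replicate 3. Of 16 macrophage genes, the mannose receptor MRC1 fell (-2.01, 2 adjusted over the list alone), with a preset adjusted p of 0.00963 and an adjusted p of 0.701 with an estimated correlation. MRC1 lost its call without any 1 of the 3 meninges units (adjusted p up to 0.119), and the complement gene C1QA had 258.6 ± 72.3 and 263.8 ± 195.7 FPKM. No T and natural killer cell gene of 14 and no neutrophil gene of 9 was called by limma, with 4 lower at an unadjusted p under 0.05 in each. Both lists passed camera with the preset correlation (adjusted p 0.00186 and 0.00394) and neither with an estimated correlation (adjusted p = 0.657 and adjusted p = 0.537). The neutrophil gene S100A9 had 273.3 ± 208.6 FPKM in meninges and 75.8 ± 120.3 in tumors, and passed without tumor replicate 7 (adjusted p = 0.0153). In the same samples the medians of the endothelial and mast cell markers were -2.43 and -2.01.

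**Figure D2:**
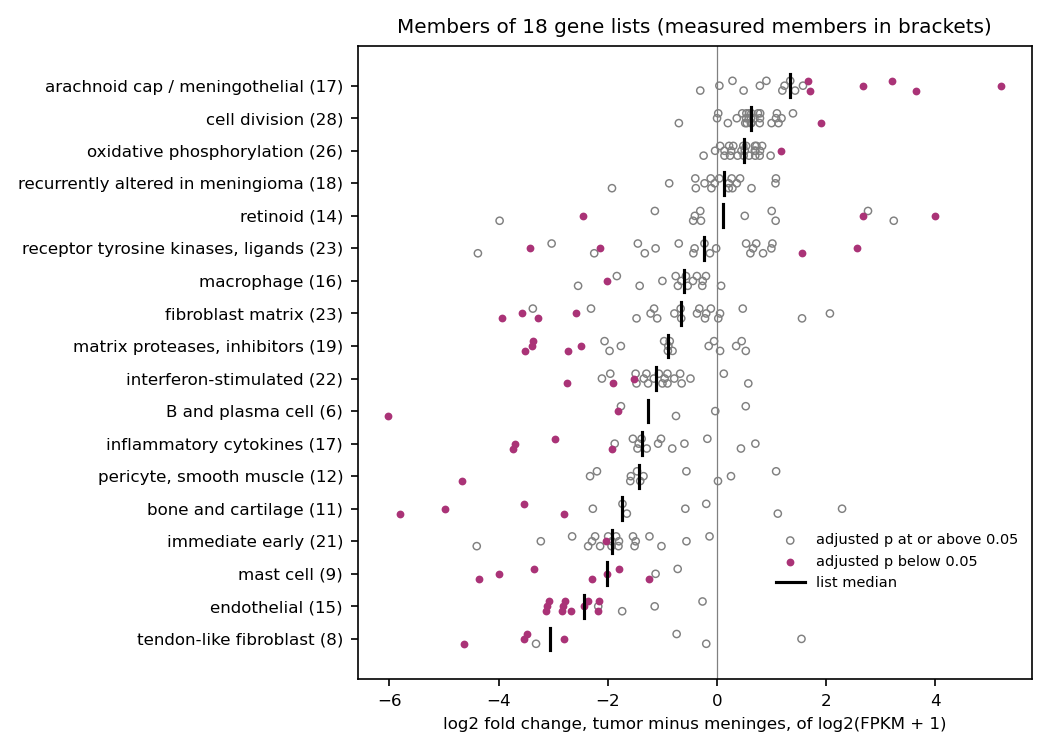
Log2 fold change of each measured member of 18 gene lists (horizontal axis, tumor minus meninges, on the log2(FPKM + 1) scale), with called genes as filled points, other genes as open points and the list median as a black bar. The medians run from -3.06 for tendon-like fibroblasts and -2.43 for endothelial cells to 1.34 for meningothelial markers.

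Signalling genes moved in both directions. Of 23 receptor tyrosine kinases and ligands, the growth factor FGF9 (0.896 ± 0.907 FPKM in meninges, 10.8 ± 6.6 in tumors, log2 fold change 2.56) and the receptor ERBB2 (18.0 ± 7.4 and 55.1 ± 23.2 FPKM, 1.55) rose. The receptor PDGFRA (36.5 ± 12.1 and 3.33 ± 3.35 FPKM, -3.43) and the ligand HGF (-2.13) fell, with 2 higher and 4 lower adjusted over the list alone and a camera adjusted p of 0.523. ERBB2 had an adjusted p of 0.132 without meninges replicate 2 and 0.0599 without meninges replicate 3. Of 14 retinoid genes, the binding proteins CRABP1 and CRABP2 rose and the retinoic acid degrading enzyme CYP26B1 fell (-2.45), with 3 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.567). CYP26B1 had an adjusted p of 0.0635 without meninges replicate 1. WNT6 was the 1 of 17 Wnt pathway genes that rose (1 adjusted over the list alone, camera adjusted p = 0.795), in a list with a median of -0.18 and a mean of 0.08. The Notch ligands DLL4 (-1.84) and JAG2 (-1.18) were the 2 of 15 Notch pathway genes that fell (3 adjusted over the list alone, camera adjusted p = 0.0589). DLL4 had an adjusted p of 0.0589 without meninges replicate 2, and JAG2 lost its call without any 1 of the 3 meninges units (up to 0.104). Of 17 genes driven by YAP and TAZ, DLC1 fell (-2.61), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.523). Of 18 TGF-beta genes, the receptor TGFBR2 fell (-1.42), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0888), and it lost its call in 8 of the 12 fits that left out 1 unit (adjusted p up to 0.183). Of 7 steroid and somatostatin receptors, the estrogen receptor ESR1 fell (3.91 ± 2.43 and 0.617 ± 0.319 FPKM, -1.49), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.523). ESR1 had an adjusted p of 0.0753 and 0.0944 without meninges replicate 1 and 3. Of 11 measured HOX genes, HOXD8 fell (-1.41, 1 adjusted over the list alone, camera adjusted p = 0.629), while the list's median was 0.68. None of 11 hedgehog pathway genes was called by limma, and 1 was higher at an unadjusted p under 0.05 (camera adjusted p = 0.501).

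Few cell division and metabolic genes were called. Of 28 cell division genes, 27 had positive log2 fold changes, with a median of 0.63, and the thymidylate synthase TYMS was the 1 called (3.59 ± 0.32 FPKM in meninges, 18.4 ± 9.7 in tumors, 1.91), also when adjusted over the list alone. TYMS had an adjusted p of 0.0681, 0.0603 and 0.0502 without meninges replicate 1, 2 and 3. The list's preset adjusted p was 1.43e-05 and its adjusted p was 0.544 with an estimated correlation. Of 26 nuclear-encoded oxidative phosphorylation genes, 24 had positive values, with a median of 0.50, and the succinate dehydrogenase subunit SDHA was called (45.3 ± 1.9 and 108.0 ± 34.8 FPKM, 1.17, 1 adjusted over the list alone). SDHA lost its call in 7 of the 12 fits that left out 1 unit (adjusted p up to 0.162), and its list had a preset adjusted p of 6.35e-05 and an adjusted p of 0.466 with an estimated correlation. No cytosolic ribosomal protein gene of 32 was called by limma or passed at an unadjusted p under 0.05. That list's median was 0.32, with a preset adjusted p of 0.0371 and an adjusted p of 0.765 with an estimated correlation. None of 17 glycolytic genes (median 0.34, camera adjusted p = 0.353), 18 genes raised by low oxygen (median 0.02, 0.629) and 16 cholesterol synthesis genes (median 0.38, 0.0768) was called by limma. At an unadjusted p under 0.05, 2 glycolytic genes were higher and 1 lower, 1 low oxygen gene was higher and 2 lower, and 2 cholesterol genes were higher. No mitochondrially encoded gene of 13 was called or passed unadjusted, and 11 had negative values, with a median of -0.43 (camera adjusted p = 0.328).

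Lists of other cell types and of the blood held few calls. The synaptic protein SYT1 fell among 9 neuron genes (1.40 ± 0.17 and 0.178 ± 0.109 FPKM, log2 fold change -1.02), with 1 higher and 3 lower adjusted over the list alone, a camera adjusted p of 0.692, a median of 0.09 and a mean of -0.04. None of 9 red blood cell genes (camera adjusted p = 0.0811), 6 astrocyte and oligodendrocyte genes (0.629), 5 Schwann cell genes (0.951) and 3 skin epithelium genes was called by limma or passed at an unadjusted p under 0.05. None of 6 platelet genes was called over all genes, 4 were lower adjusted over the list alone, and the camera adjusted p was 0.0767. Of 4 skeletal muscle genes and 4 choroid plexus genes none was called by limma, and 1 of each was higher and 1 lower at an unadjusted p under 0.05. The skeletal muscle troponin TNNT1 had 1.75 ± 0.27 FPKM in meninges and 78.3 ± 121.3 in tumors (2.96, SE 1.25). None of 16 complement genes (camera adjusted p = 0.863) and 13 heat shock genes (0.0691) was called by limma, with 1 and 0 higher and 2 and 2 lower at an unadjusted p under 0.05. Over all 44 lists tested, 4 were called higher and 16 lower with the preset correlation, and 0 higher and 2 lower with an estimated one, where 1 higher and 7 lower passed unadjusted.

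Technical libraries of a specimen resembled each other more than libraries of different specimens did. Over genes, Pearson's r of log2(FPKM + 1) had a median of 0.993 in 38 pairs of libraries from the same specimen, 0.926 in 493 pairs from different units of a group and 0.900 in 231 pairs of a tumor and a meninges library. A median of 93% of the variance of a gene among tumor libraries lay between specimens, and 92.5% among meninges libraries. Mitochondrially encoded genes held 18.4% ± 3.4 of the FPKM sum in meninges (SD, n = 3) and 15.4% ± 8.0 in tumors (SD, n = 9, exact two-sided permutation p = 0.56). Hemoglobin genes held 0.557% ± 0.294 and 0.347% ± 0.757 (exact permutation p = 0.64), and ribosomal protein genes 19.0% ± 1.2 and 23.4% ± 6.4 (exact permutation p = 0.27). A library had a mean of 13279 ± 370 genes at an FPKM of at least 1 in meninges and 12923 ± 165 in tumors (exact permutation p = 0.027, adjusted over 5 measures 0.14). The smallest p these 220 assignments allow is 0.0045.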

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

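In 16 of 95 values tested, the highest of the 9 tumors stood apart from the other 8, with a gap to its nearest neighbour that made up more of the whole range than Dixon's 95% critical value. For normally distributed values, chance flags about 1 in 20. Several flagged genes had values near 0 in the other tumors, where a value can stand apart upward but hardly downward. That rate therefore does not hold for them. No value was flagged for a lowest tumor, and the 14 genes among them were highest in 6 different tumors, with at most 4 genes in the same tumor. Gaps of genes were taken on the log2(FPKM + 1) scale. Among connective tissue genes, the share of the range was 0.768 for ACAN (highest tumor 14.0 FPKM, next 1.14), 0.761 for COL10A1 (3.11, next 0.598), 0.669 for ADAMTS1 (65.6, next 10.9), 0.549 for MKX (1.73, next 0.660) and 0.542 for DPP4 (1.39, next 0.498). Among mast and plasma cell genes it was 0.773 for TPSB2 (12.6 FPKM, next 1.28), 0.628 for CPA3 (6.60, next 1.29) and 0.622 for MZB1 (1.31, next 0.432). The share was 0.551 for CXCL2 (9.59 FPKM, next 2.83), 0.526 for S100A9 (393.7, next 64.1), 0.506 for MYC (58.6, next 30.2) and 0.524 for the adipocyte gene AQP7 (6.58, next 2.25). It was 0.618 for CYP26B1 (8.33 FPKM, next 2.59) and 0.533 for MUC1 (214.2, next 44.6). Among library measures, 1 tumor had 2.36% of its FPKM sum in hemoglobin genes, with the next at 0.180% (share of the range 0.941). An FPKM sum of 1548520 stood apart from the next at 1065730 (0.574).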

How the results depend on the processing

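No called gene named and no called list changed sign under any alternative run. Of the uncalled genes of the rule that are printed here, PGR changed sign (-0.92 with the replicate block). The medians of 15 lists also changed sign in at least 1 setting. So did several uncalled genes of the rule that are not printed elsewhere, such as ENO1 (-0.342, and 0.319 without meninges replicate 2). CDH5 was not followed through the alternatives. Leaving out 1 unit at a time gave 42 to 180 higher and 312 to 539 lower genes against 126 and 494, and 42 to 177 and 310 to 530 at 2-fold or more against 125 and 488. The higher count was 62, 42 and 51 without meninges replicate 1, 2 and 3, and the lower count 312 without meninges replicate 1. Of the 81 called genes named, 43 kept their call in every such fit. A mean FPKM of at least 5 left 226 lower genes, all at 2-fold or more, and 102 higher genes, with 10401 genes tested against 14279. The mean is taken over the 12 units, of which 9 are tumors, so the filter bears more on genes low in tumor. The cause of the larger fall among lower genes was not tested. Treating the 40 libraries as independent gave 1798 higher and 2288 lower genes (709 and 1193 at 2-fold or more), because technical libraries then count as samples. With the unit as a random effect there were 420 and 770 (321 higher at 2-fold or more), and weighting units by quality gave 381 and 976 (268 and 847). For both, the cause was not tested. Only 2 title numbers occur in both groups, and the labels do not say that they pair specimens, which was not examined. With the title number as a replicate block there were 49 and 194 genes, all at 2-fold or more, of which 17 and 134 were among the main calls. In that fit, with 1 residual degree of freedom, only the units with those 2 numbers set the tumor difference, and the other units added nothing to it. There 40 of the 81 called genes named lost their call, which is not a test over all 12 units. Median-of-ratios scaling moved nothing and so tests nothing. Gene lists called went from 4 higher and 16 lower to 0 and 2 with an estimated correlation, because members vary together, and to 1 and 9 with fry, which tests a list without comparing it with other genes. The other planned settings stayed within 1.5 times the main counts. Without 6 libraries with over 30% mitochondrial FPKM, a setting chosen after seeing the data, 107 genes were higher and 482 lower. These libraries were all those of tumor replicate 7 and those of 1 of the 2 specimens of tumor replicate 9. The setting therefore drops a tumor, and it is close to the fit without tumor replicate 7, which gave 107 and 466. The share of variance between specimens was 92.3% to 94.8%. Over the 14279 genes, the median SD between technical libraries of a specimen was 0.155 in tumors and 0.11 in meninges on the log2(FPKM + 1) scale. The error of low genes was not measured apart from that of the others.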

Other observations

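Antibody genes other than JCHAIN were also lower in tumor. All 7 measured members of an immunoglobulin list, JCHAIN among them, fell, with a median log2 fold change of -5.45. The kappa light chain constant gene IGKC had 868.9 ± 454.2 FPKM in meninges (SD, n = 3) and 18.6 ± 13.0 in tumors (SD, n = 9), and the heavy chain gene IGHG2 54.7 ± 26.5 and 0.115 ± 0.102, with reads of such copies hard to separate. Of 8 metallothioneins, which bind zinc and copper, 6 fell as well, and the median of the 8 was -3.78. MT2A had 6960 ± 7564 FPKM in meninges and 257.9 ± 214.4 in tumors (limma adjusted p = 0.0036). Both lists were written, and these genes chosen, after their values were seen, so no set test is given for them.

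Among the other genes higher in tumor were several regulators, chosen after their values were seen and not rerun under the alternatives. The cyclin CCND1 had 37.8 ± 7.7 FPKM in meninges (n = 3) and 235.9 ± 128.7 in tumors (n = 9), a log2 fold change of 2.36 (limma adjusted p = 0.0087). The transcription factors ZIC2 (16.9 ± 10.7 and 77.9 ± 28.5 FPKM, 2.25) and FOXD2 (5.04 ± 1.44 and 30.1 ± 10.8 FPKM, 2.30) and the Wnt receptor FZD2 (2.05 ± 0.93 and 19.2 ± 8.7 FPKM, 2.67) were higher in all 9 tumors than in all 3 meninges. So were SREBF1, a regulator of lipid synthesis (7.61 ± 2.55 and 46.0 ± 25.9 FPKM, 2.30), and the keratin KRT19 (3.96 ± 1.62 and 29.2 ± 14.1 FPKM, 2.46). The heart and smooth muscle calcium pump regulator PLN (28.8 ± 21.0 and 0.309 ± 0.143 FPKM, -4.13) and the endothelial receptor S1PR1 (59.3 ± 20.6 and 3.46 ± 1.70 FPKM, -3.85) were lower in all 9.

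In the patterns that follow, the tests of cell-type lists among the lower genes, of the summed metallothionein level and of heat shock genes were chosen after the results were seen. Of 620 called genes, 79.7% were lower in tumor, a share that was 68.9% at a mean FPKM of at least 5, 64.7% with the unit as a random effect and 56% with the 40 libraries as independent. Scaling was argued against as the whole cause, since at least 72.3% of calls were lower under median-of-ratios scaling (which moves nothing), quantile normalization and with mitochondrial, hemoglobin and ribosomal protein genes taken out. Less RNA of vessel, connective tissue, mast and plasma cells in the tumors stays open: the odds ratio of their lists among the lower calls was 17.73, but these lists were pooled after they were seen to hold lower calls, so it decides nothing, and they hold 35 genes, or 7.1% of the lower calls. A larger spread among tumors of the higher genes stays open too, as does the difference in tissue itself: without a test, 1297 genes were at least 2-fold lower and 748 higher, a ratio of 1.73, and their median SD among tumors was 0.751 and 0.941. Of the 220 possible splits of the 12 units into 3 and 9, 100 were run, the real one included. The real one alone (1) gave as many as 620 genes and the highest other gave 46, so chance is unlikely for the gene count, though not excluded. For lists, 7 splits gave at least the 20 called, the highest other 22, so chance cannot be excluded for the list count with the preset correlation.

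Chromosome 22 genes had a median log2 fold change of -0.19 (bootstrap SE 0.030, 350 genes), the second lowest of the 22 autosomes. Per unit, the median shift of chromosome 22 was -0.206 (SE 0.123, exact two-sided permutation p = 0.37), which does not pass a test, and 5 of 9 tumors lay below all 3 meninges. Removing a smooth GC trend left a shift of -0.288 (SE 0.114, exact permutation p = 0.15), below 0 by more than 2 SE. The shift passed no exact test before or after that step, so the role of GC content stays undecided. The gene-dense chromosomes 16, 17 and 19 had medians at least 0.296 higher. That gap was set against a spread over genes and not over units, so whether gene-dense chromosomes moved together stays undecided. Loss of 1 copy in part of the tumors may contribute but cannot be told apart from other regional differences, because chromosome 22 ranked 2 and chromosome 4 was lowest at -0.22 (SE 0.031), a gap within their spread.

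Of 8 metallothionein genes, 6 were called lower in tumor, while MT1G (log2 fold change -1.95, limma adjusted p = 0.11) and MT1H (0.51, 0.525) were not called. Reads moving between near-identical copies were argued against as the cause, because the summed FPKM of the 8 genes was 10271 ± 9635 in meninges (n = 3) and 516.9 ± 420.4 in tumors (n = 9), a log2 difference of -3.983 (SE 1.059). Glucocorticoid exposure of the meninges specimens may raise these genes but cannot be told apart from no exposure, since a list of 16 other response genes had a median of -0.38 (estimated correlation p = 0.282) and 1 called member, MAOA. A general stress response stays open for the same reason, with a heat shock list at a median of -0.50 (estimated correlation p = 0.319). The labels do not give how the specimens were handled between resection and freezing, and the difference in tissue itself was not tested apart from these.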
